A study of Homo sapiens with 4 samples.

How the data were processed

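FLASH-seq was run on 4 libraries of RPE1 cells, 2 from CFAP20 knockout cells (CFAP20-KO) and 2 from the same knockout cells expressing a biotin-tagged CFAP20 (tagged-CFAP20). Per the labels' protocols, cells were crosslinked with UV-C light, lysed and sonicated, protein was captured on streptavidin beads, RNA was trimmed with RNase I, and a barcoded adapter was ligated before reverse transcription and amplification. Groups and replicate numbers come from the sample titles. Per the submitters' processing notes, the tools were UMI-tools 1.0.0, Bowtie2 2.3.5, HOMER 4.8.2 and R 4.0.5 with the hg38 build, listed without their roles or order, so read trimming, duplicate removal, mapping settings and normalization are not given in the sources used here.

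The authors deposited 1 table of signal (read coverage) per library, with a gene per line. Its 200-bp bins run from 50 kb upstream to 100 kb downstream of the gene start, although the table names give a 200-kb window. By their names and values the tables hold genes of at least 3 kb with a gap of at least 2 kb to the neighbouring gene. The other deposited columns of the tables, of unit other, describe the gene (position, strand and length). In each table every value was a whole multiple of 1 step (100.0% of values within a tolerance of 0.01), 83.0 and 276.88 in CFAP20-KO replicates 1 and 2 and 12.85 and 13.93 in tagged-CFAP20 replicates 1 and 2. The step was taken as 1 read overlapping a bin, and values divided by it are called read overlaps. A read that spans 2 bins is in both, and 1 read covered 1.38 bins on average by comparison of adjoining bins, so read overlaps are not whole-read counts. No model of whole-read counts was fitted, and the exact tests and intervals below use overlaps divided to allow for this. If the authors scaled each library to the total that HOMER uses by default, the steps imply libraries of 160643, 48156, 1037344 and 956938 reads; neither this target nor the read length is stated, and no result uses it. A difference in signal between groups is therefore relative to a normalization that is not stated, and a common factor per library cannot be seen in it. The signal is not split by strand, since overlapping windows of neighbours on opposite strands gave nearly the same values (r of at least 0.971 across genes in each library), so antisense and overlapping genes cannot be told apart. Genes missing from a table were set to 0 after a check in which 207 of 207 such genes, seen through a neighbour's window, had 0 reads. Of 9667 identifiers, 9478 were matched to symbols of GENCODE 44. A further column, 1 in number, matched no sample label and was not used.

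Signal was summed per gene from its start to its end within 100 kb downstream. The test fixed before the data were examined assumed counts or normalized values. The values were a normalized signal, so limma 3.58.1 in R 4.3.3 (trend, moderated) was run on log2(signal sum + 10) with no further scaling, on the 4461 genes above 0 in at least 2 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The pseudocount is under 1 CFAP20-KO read, so for genes at 0 in CFAP20-KO the log2 change follows the pseudocount and is no bound. Where both CFAP20-KO libraries were at 0, the fold is given against the signal of 3 reads pooled over both, 264.0, as a lower bound. This bound is a counting limit for a gene taken alone and does not allow for the choice of genes by their change. For named genes with 1 to 3 CFAP20-KO overlaps, the ratio of pooled reads is given with its 95% exact counting interval. Named genes followed a rule set in advance. CFAP20 came first, then the 10 genes with the largest change in each direction among those past the threshold whose groups do not overlap and whose mean signal lies above the median of the genes tested, filled by the smallest unadjusted p, then the 10 with most signal in each group, and the 3 members of each list with most signal. A gene that this rule names is not reported here. Beside a gene whose groups do not overlap, chance gives that 1 time in 3. The 19 gene lists, fixed in advance, were ribosomal proteins, translation factors, snoRNA host genes, nuclear long noncoding RNAs, extracellular matrix and mesenchymal genes, cytoskeleton, splicing factors and hnRNPs, RNA polymerase II and elongation, DNA replication, motile cilium and CFAP genes, intraflagellar transport, biotin-dependent carboxylases, immediate early genes, p53 targets, nuclear-encoded oxidative phosphorylation, heat shock genes, and markers of blood, neurons and liver. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry.

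Regions were the first 1 kb from the gene start, 5 to 50 kb downstream in genes at least 50 kb long, and 50 to 5 kb upstream. Group means are given with SD and n = 2, with an exact two-sided permutation test over the 6 assignments, whose smallest p is 0.333. Bins were also joined into non-overlapping 200-bp tiles of the genome and given the annotation from GENCODE 44 that they touch, the first in the order small RNA gene, coding exon, 3′ UTR, 5′ UTR, long noncoding RNA exon, other exon, intron, between genes. Shares have 95% exact (Clopper-Pearson) intervals, made on read overlaps divided by 1.38. Odds ratios within genes are Mantel-Haenszel ratios with intervals from 1000 bootstrap draws of genes.

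Added after the data were seen was an exact two-sided binomial test of read overlaps pooled per group, on the deposited scale and as shares of the gene signal. Overlaps were divided by 1.76, the product of the bins per read and the largest chi-square per degree of freedom over gene sums within a group (1.28), and genes with at least 10 such reads were tested. Single bins were compared between replicates where a pair had at least 50 overlaps. The exact test measures counting error widened by the divisor, not the spread between cultures. The same share test was run on all annotated genes with at least 60 overlaps.

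The fits were tested on simulated data with the real depths and a dispersion of 0.02, a set value that was not fitted to the data. With 200 genes changed, limma recovered 70% of 8-fold and 68% of 4-fold increases and 8% and 0% of such decreases. The exact test of shares recovered 94.0% and 32.0% of such increases and 62.9% and 36.0% of such decreases. The changed genes were drawn only from genes with many read overlaps, so these rates do not hold for genes with few. With equal shares in all libraries limma called 1434 of 4030 genes, and the exact test called 145 of 2768 on the deposited scale and 0 as shares. Alternatives to each result covered scaling (quantile normalization, which called 0 genes with 712 at an unadjusted p under 0.05, and equal window totals), pseudocount, filters, trend, summed region, capped bins, trimmed means, gene sets, a replicate block and leaving out each library. Added after the data were seen were a pseudocount of 1 read of the shallowest library, thinning, precision weights, a filter on mean reads and the exact tests. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.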

Results

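RNA held by ultraviolet crosslinks was sequenced from 4 libraries of RPE1 cells, an immortalised line from human retinal pigment epithelium that here lacked p53 and carried an inducible Cas9. In FLASH-seq, ultraviolet light links proteins to the RNA they touch, a biotin-tagged protein is pulled down on streptavidin beads, RNase I trims the bound RNA, and the remaining fragments are sequenced. The 2 tagged-CFAP20 libraries came from CFAP20 knockout cells that expressed a biotin-tagged CFAP20. The 2 CFAP20-KO libraries came from the knockout cells without the tagged protein and were the negative control. CFAP20 is a protein of cilia and flagella, and the series asks whether it also binds RNA. The labels do not say that replicates came from separate cultures. The p-values of limma and of the permutation tests therefore measure the spread between these libraries, which may be technical. Exact binomial tests pool the 2 libraries of a group, so their p-values measure counting error widened by a divisor, rather than that spread.

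Depth differed strongly between the groups. Reads overlapped the bins of the deposited gene windows 36303 and 15453 times in the CFAP20-KO libraries, against 655566 and 530538 times in the tagged-CFAP20 libraries. Of 9667 genes, 2361 and 1479 had signal between their start and end in the CFAP20-KO libraries, against 5212 and 5092 in the tagged-CFAP20 libraries. A gene at 0 can hide the signal of up to 3 reads, which is 343 and 1145 in CFAP20-KO replicates 1 and 2, and 53.1 and 57.6 in tagged-CFAP20 replicates 1 and 2. These floors, and the intervals given here, cover counting error only.

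CFAP20, the gene knocked out and put back as the tagged protein, was covered on its coding exons in both tagged-CFAP20 libraries and in neither CFAP20-KO library. The gene lies on the minus strand of chromosome 16 from 58113592 to 58129381 (hg38). The bins read here belong to the window of the neighbouring gene MMP15 and cover 76.5% of CFAP20, with exons 2 to 6 and the 3′ UTR. Its coding bins held 36 and 38 read overlaps in the tagged-CFAP20 libraries, a signal of 496 ± 47.2 (SD, n = 2), and 0 in each CFAP20-KO library. Against the floor of 3 reads pooled over both CFAP20-KO libraries, 264.0, the coding signal was at least 1.88-fold higher with the tagged protein. Intron bins held 7 and 1 overlaps in the tagged-CFAP20 libraries, and the 3′ UTR bins held 0 in all 4 libraries. At the depth of the CFAP20-KO libraries, the share of reads seen on the coding bins in the tagged-CFAP20 libraries would have given 3.23 overlaps, with a probability of 0.0960 of seeing 0, so a difference in share was not detectable here.

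**Figure D1:**
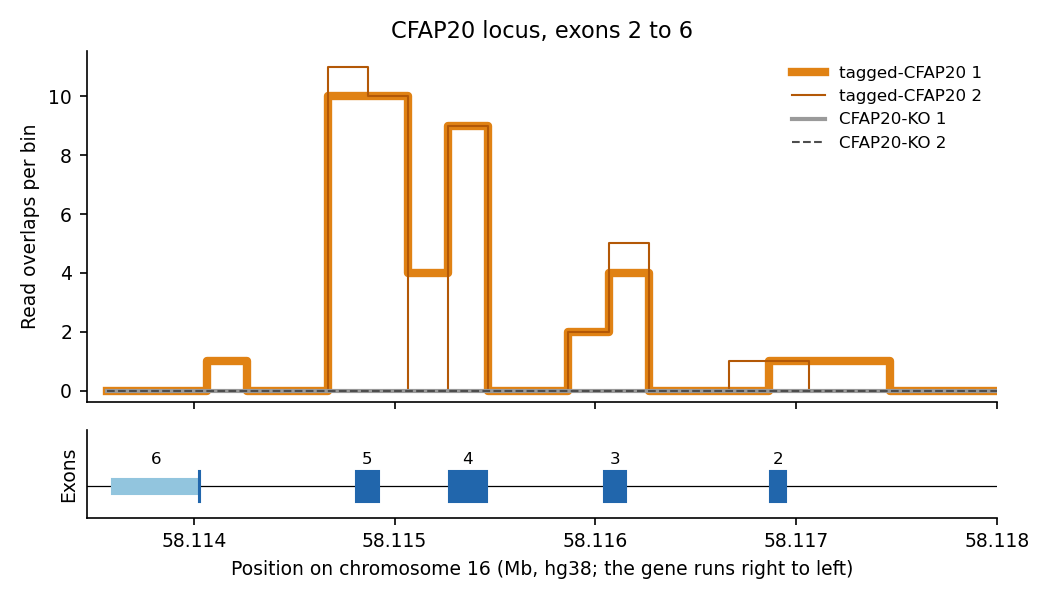
CFAP20 locus on chromosome 16 (hg38, position in Mb), with read overlaps per 200-bp bin as 1 line per library above and the annotated exons below, coding parts dark and the 3′ UTR light. The tagged-CFAP20 libraries, with 36 and 38 overlaps, peak over the coding exons, and both CFAP20-KO libraries lie at 0 across the locus.

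The main comparison asked which RNAs came down with tagged CFAP20 above the background of the same pull-down without it. Summed over genes, signal was higher with the tagged protein, at 2001262 ± 172361 against 920583 ± 228345 in CFAP20-KO (SD, n = 2 each), a ratio of 2.17. In limma, 1681 of 4461 genes tested passed an adjusted p of 0.05, of which 1678 were higher and 3 lower with the tagged protein. Of the 1678, 1589 were at 0 in both CFAP20-KO libraries, and 1390 of these had a signal with the tagged protein under the floor of 264.0, so that the knockout could hide as much. Of the 10 named genes with the largest positive change, TOPBP1, a scaffold of the replication checkpoint, had most signal. It stood at 1553 ± 167 (SD, n = 2) with the tagged protein and 0 in both CFAP20-KO libraries, at least 5.88-fold higher. The folds of these 10 genes are against the floor of 264.0, which does not allow for their choice among many genes at 0 in CFAP20-KO. KIF14, a kinesin of cytokinesis, was at least 5.33-fold higher. MCM3, a subunit of the replicative helicase, was at least 3.52-fold higher, as was BRCA1, a homologous recombination factor, by at least 3.20-fold, and NDC80, part of the outer kinetochore, by at least 3.05-fold.

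The remaining genes among these 10 were likewise at 0 in both CFAP20-KO libraries. They were GLRX3, a glutaredoxin (at least 5.50-fold higher), NOC3L, a nucleolar protein (at least 5.48-fold), NFRKB, a subunit of the INO80 remodeller (at least 3.58-fold), XYLB, xylulokinase (at least 3.34-fold), and JADE1, a scaffold of an acetyltransferase complex (at least 3.29-fold). Limma adjusted p ran from 0.00597 to 0.00619, and no log2 change is given for them, since with 0 in CFAP20-KO it follows the pseudocount, from 7.28 for TOPBP1 in the main fit to 2.72 with a pseudocount of 1 read. For all 10 genes an exact binomial test of pooled reads, chosen after seeing the data because it allows for depth, gave an adjusted p between 0.000299 (TOPBP1) and 0.0349 (NDC80). As shares of each library's gene signal, the same test gave adjusted p from 0.869 to 1.0 for them, while limma with precision weights on the window total scale called all 10 higher, with adjusted p from 0.00153 (TOPBP1) to 0.0430 (NDC80). Quantile normalization lost the call for all 10, summing over the whole downstream side for 7 (TOPBP1 adjusted p = 0.139, NDC80 0.259) and thinning for 2.

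Within the deposited gene set, the strongest signals with the tagged protein included those on FLNA, HNRNPH1, RBM39, SETD5, CAPN2, MKI67, SLC4A7, PLK2 and HPCAL1. HNRNPH1, an RNA-binding protein of pre-mRNA splicing (chromosome 5, gene start 179624669), reached 10484 ± 1861 (SD, n = 2) against 2104 ± 1332 in CFAP20-KO, a 4.98-fold difference (log2 change 2.46, SE 0.56, limma adjusted p = 0.0474). It also rose as a share of the gene signal, from 0.153% and 0.281% in CFAP20-KO to 0.556% and 0.488% (exact binomial test, adjusted p = 0.00609). RBM39, a splicing factor, was 4.88-fold higher (9454 ± 1409 against 1938 ± 392, limma adjusted p = 0.00597). PLK2, a polo-like kinase, was 4.49-fold higher (limma adjusted p = 0.0133), SLC4A7, a bicarbonate transporter, 3.37-fold (limma adjusted p = 0.00597), and SETD5, a SET-domain protein, 2.47-fold (limma adjusted p = 0.00975). The largest signal of this gene set in both groups was on FLNA, the actin crosslinker filamin A, with 15686 ± 1848 against 6242 ± 3311, which did not pass in limma (adjusted p = 0.101). CAPN2, MKI67 and HPCAL1 had 2.14, 2.26 and 4.46 times the CFAP20-KO signal and did not pass either, with limma adjusted p from 0.0508 (HPCAL1) to 0.309 (CAPN2). In the exact test on the deposited scale, chosen after seeing the data, all 4 were higher with the tagged protein, with adjusted p from 2.00e-16 (FLNA) to 7.55e-08 (HPCAL1), but as shares the same test gave each an adjusted p of 1.0. Of the other genes in this paragraph, RBM39 (0.1896), PLK2 (0.737), SLC4A7 (1.0) and SETD5 (1.0) did not pass as shares either.

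Within the same gene set, the strongest signals in CFAP20-KO lay on FLNA, PRR16, EXT1, CAPN2, ITGA11, PICALM, SETD5, MKI67, TGM2 and ZMIZ1. Of those not yet described, EXT1, a heparan sulfate polymerase, was 1.45-fold higher with the tagged protein (5337 ± 159 against 3681 ± 276.0, SD, n = 2, limma adjusted p = 0.0162), and ZMIZ1, a transcriptional coregulator, 2.16-fold (limma adjusted p = 0.00767). After scaling to the same window total both lay on the other side, at log2 changes of -0.60 and -0.024. ITGA11, PICALM and TGM2 had tagged over CFAP20-KO ratios of 1.204, 1.44 and 1.87 and did not pass in limma, while TGM2 passed as higher in the exact test on the deposited scale (adjusted p = 0.00164). With the same window totals ITGA11 and PICALM passed as lower, at log2 changes of -0.86 (limma adjusted p = 0.0126) and -0.59 (0.00834).

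The 3 genes that passed in the other direction were NORAD, ENSG00000272369 and IRAG1. NORAD, a long noncoding RNA that binds Pumilio proteins (chromosome 20, gene start 36050960), fell to 0.152 times the CFAP20-KO signal (206 ± 54.5 against 1356 ± 39.9, SD, n = 2, log2 change -2.69, SE 0.51, limma adjusted p = 0.0310). The long noncoding RNA gene ENSG00000272369 on chromosome 12 fell to 0.376 times (log2 change -1.39, SE 0.24, limma adjusted p = 0.0231). IRAG1, named after its values were seen because only 3 genes fell, rested on 2 and 1 read overlaps in CFAP20-KO and 1 each in the tagged-CFAP20 libraries. With a replicate block limma called 0 genes lower, so all 3 lost the call (NORAD adjusted p = 0.165, ENSG00000272369 0.0712). NORAD also lost the call with no filter (limma adjusted p = 0.0642) and after thinning (0.116). ENSG00000272369 lost it in limma without trend (adjusted p = 0.0580), and over the first 3 kb its log2 change was 1.95. Next by unadjusted p, and not past the threshold, were LINC01242, LOX, ODAD1, LINC00539, ENSG00000260808, ERCC6L, PRR16 and ACOT2, with log2 changes between -0.51 (PRR16) and -4.06 (LINC01242) and limma adjusted p between 0.0720 and 0.193. With precision weights on the window total scale, a fit that called unchanged genes lower in simulation, limma called all 8 lower, and on the deposited scale LINC01242, ODAD1, LINC00539 and ENSG00000260808. As a share of the gene signal, LOX, the collagen crosslinking enzyme lysyl oxidase, fell from 0.197% and 0.179% to 0.0357% and 0.0497% (exact binomial test, adjusted p = 0.0103), and PRR16, a regulator of cell size, from 0.481% and 0.486% to 0.150% and 0.158% (adjusted p = 2.38e-05).

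The number of genes called depended on how depth and scaling were handled. In simulated libraries with the same signal and the real depths, limma called 650 of 3867 genes, while the exact test called 0 of 2565. With equal shares instead, limma called 1434 of 4030. The exact test then called 145 of 2768 on the deposited scale, all higher, and 0 as shares. In the real libraries the exact test called 193 of 2823 genes on the deposited scale, 191 higher and 2 lower with the tagged protein. As shares of the gene signal it called 8, with HNRNPH1 and the kinesin CENPE higher and NORAD, ENSG00000272369, PRR16, PRSS23, EFEMP1 and LOX lower, and 100 genes had an unadjusted p under 0.05. Without CFAP20-KO replicate 1 it called 0 genes on either scale, and without CFAP20-KO replicate 2 it called 131 on the deposited scale and 4 as shares. Limma called 0 genes without either tagged-CFAP20 replicate, and 3674 and 3226 without CFAP20-KO replicates 1 and 2. With the same window totals limma called 1483 genes, 1451 higher and 32 lower, a setting not run on the simulated libraries. With precision weights and scaling to the window total, limma called 23 genes higher and 272 lower. In simulated libraries with equal shares that fit called 121 of 4030 unchanged genes, 120 of them lower. The median log2 change over the genes tested was 2.10 in the main fit and 1.57 with the same window totals, but 0.37 with a pseudocount of 1 read, 0.35 with precision weights, -0.13 with quantile normalization and -0.83 with weights on the window total scale.

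Gene lists fixed before the data were examined were compared next. Where a member had 1 to 3 read overlaps in CFAP20-KO, the value given is the pooled-read ratio with its 95% exact counting interval in brackets, which can differ from the ratio of mean signals. Passing here means in limma unless another test is named. Over all genes tested, 1678 of 4461 passed upwards, and the ratio of the summed gene signal was 2.17. Lists near these values are not set apart from other genes. The splicing factors and hnRNPs had 8 of 12 tested members higher and 0 lower (9 adjusted over the list alone). HNRNPH1 and RBM39 are described above, and the helicase DDX17 was 2.29-fold higher (limma adjusted p = 0.00900) with a log2 change of -0.11 under precision weights on the window total scale. The signal summed over this list was 3.65-fold higher with the tagged protein (45749 ± 5703 against 12538 ± 1064, SD, n = 2), and its share of the gene signal went from 1.55% and 1.23% to 2.34% and 2.22%. Camera, which compares a list with the other genes, gave an adjusted p of 0.437, or 0.724 with an estimated correlation. It passed without CFAP20-KO replicate 2 (adjusted p = 0.00147) and without tagged-CFAP20 replicates 1 (1.09e-11) and 2 (6.03e-13).

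Of the DNA replication genes, 2 of 8 rose (2 adjusted over the list alone), MCM3 among them, and the summed signal was 3.82-fold higher. That ratio rests on 5 and 4 read overlaps in CFAP20-KO replicates 1 and 2. CDC45 and MCM2, helicase components, did not pass, with pooled-read ratios of 12.04 (1.67 to 1608) and 4.50 (0.598 to 611.6). Immediate early genes had 5 of 9 members past the threshold upwards (5 adjusted over the list alone), each of them under the floor, and a summed ratio of 2.48. Their members with most signal did not pass. MYC stood at 1.31 times the CFAP20-KO signal, and the pooled-read ratios of KLF6 and EGR1, 11.4 (1.58 to 1525) and 4.19 (0.554 to 570.1), rest on 1 CFAP20-KO overlap each. Of the RNA polymerase II and elongation genes, 1 of 5 passed upwards (1 adjusted over the list alone), also under the floor. The elongation factor SUPT5H was at 2.36 times the CFAP20-KO signal and did not pass (limma adjusted p = 0.103), nor did CCNT1 at 1.36 times and LEO1 at 2.04 times.

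Cilium genes were read because CFAP20 is a ciliary protein. Of the motile cilium and CFAP genes 2 of 5 passed upwards (2 adjusted over the list alone), with a summed ratio of 4.77. Of the intraflagellar transport genes 4 of 9 did (4 adjusted over the list alone), with a summed ratio of 2.28. Of the members that passed, 2 and 3 were under the floor. The first summed ratio rests on 4 and 1 read overlaps in CFAP20-KO replicates 1 and 2, and the second on 16 and 12. The named members did not pass in limma. The pooled-read ratios of CFAP299, CFAP251 and CFAP54 were 5.65 (1.26 to 85.6), 3.25 (0.704 to 49.7) and 4.29 (0.569 to 583.9, exact counting intervals), on 2, 2 and 1 CFAP20-KO overlaps. The dynein DYNC2H1 stood at 2.62 times the CFAP20-KO signal, IFT81 at 1.93 and IFT43 at 0.452.

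Ribosomal protein genes had 3 of 14 members past the threshold upwards (3 adjusted over the list alone), 2 of them under the floor, and a summed ratio of 2.48. RPS24 stood at 4.89 and RPS4X at 0.819 times the CFAP20-KO signal, and RPL37A had a pooled-read ratio of 3.30 (0.716 to 50.4), none past the threshold, and these genes share sequence with processed pseudogenes, so their values are uncertain. None of the 8 translation factors passed (0 adjusted over the list alone), with a summed ratio of 2.64, ratios of 2.19 for EIF3B and 1.77 for EEF1A1, and a pooled-read ratio of 4.96 (1.401 to 36.5) for EIF2S3. Oxidative phosphorylation genes had 2 of 9 members past the threshold upwards (2 adjusted over the list alone), both under the floor, and a summed ratio of 1.66. NDUFA10 stood at 1.73 and UQCRC1 at 3.09 times the CFAP20-KO signal, and COX7C had a pooled-read ratio of 0.419 (0.0895 to 3.54), none past the threshold.

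The extracellular matrix and mesenchymal genes, which RPE1 cells express, had 0 of 8 members past the threshold (0 adjusted over the list alone) and a summed ratio of 1.88. CCN1 and COL12A1 stood at 1.98 and 3.07 times the CFAP20-KO signal. Camera placed this list lowest, with an adjusted p of 0.115 (0.724 with an estimated correlation), although its median log2 change was positive at 0.27. None of the 3 cytoskeleton genes passed (0 adjusted over the list alone; summed ratio 2.41), with CALD1 at 1.25 times the CFAP20-KO signal and a pooled-read ratio of 5.55 (0.748 to 750.01) for TUBA1A. None of the 4 heat shock genes passed (0 adjusted over the list alone, summed ratio 2.07). HSP90AA1 and BAG3 stood at 2.21 and 1.57 times the CFAP20-KO signal, and HSPH1 had a pooled-read ratio of 4.29 (1.21 to 31.7). The summed CFAP20-KO signal of this list was 1979 ± 1508 (SD, n = 2), on 11 read overlaps in each library. Of the p53 targets 1 of 4 passed upwards in limma (2 adjusted over the list alone). This was ZMAT3, at 228 ± 31.9 (SD, n = 2) against 0, which is under the pooled CFAP20-KO floor of 264.0, and it did not pass in the exact test (adjusted p = 0.709). SESN2 and BAX did not pass, with pooled-read ratios of 5.03 (0.673 to 680.8) and 1.26 (0.2499 to 19.99, both exact counting intervals). BAX has no clear direction, since its ratio of mean signals was 0.575.

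The 3 measured members of the list named nuclear long noncoding RNAs went both ways (2 adjusted over the list alone). NORAD was lower, and CCAT1 passed the threshold upwards on 1 read overlap in each tagged-CFAP20 library. OIP5-AS1 had a pooled-read ratio of 4.61 (exact counting interval 0.613 to 625.4) and did not pass. The summed signal of these 3 was 0.344 times that of CFAP20-KO. MALAT1 and NEAT1, also on the list, are outside the deposited gene set, so this sum does not cover them. Of the biotin-dependent carboxylases only PCCB was measured. It had a pooled-read ratio of 1.501 (exact counting interval 0.400 to 11.4) and did not pass (0 of 1, and 0 adjusted over the list alone). Markers of cells that the culture should lack were read too. The 3 blood cell genes and the 4 liver genes had 0 signal in CFAP20-KO and a mean of 6.97 with the tagged protein for each list, which is 1 read overlap. The neuron marker SNAP25 passed (1 of 1 tested, 1 adjusted over the list alone), at 175 ± 47.8 (SD, n = 2) against 0, which is over the tagged-CFAP20 floors and under the pooled CFAP20-KO floor of 264.0. Of the snoRNA host genes, 0 entered the gene test, and GAS5, read through a neighbour's window, is given among the other observations. Camera called 0 of the 10 lists with at least 5 tested members, with 1 at an unadjusted p under 0.05.

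Some named list members that did not pass in limma did so in tests chosen after seeing the data. In the exact test on the deposited scale these were COL12A1 (adjusted p = 9.98e-07), SUPT5H (5.81e-05), CCN1 (0.00448), DYNC2H1 (0.0115) and HSP90AA1 (0.0227), each higher with the tagged protein and with an adjusted p of 1.0 as shares. With limma's precision weights on the deposited scale, COL12A1, DYNC2H1, HSP90AA1, CDC45, KLF6 and RPS24 passed as higher, with adjusted p from 0.0119 (COL12A1) to 0.0384 (HSP90AA1). On the window total scale, where the fit called unchanged genes lower in simulation, those weights called IFT43 (0.0239) and COX7C (0.0365) lower.

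**Figure D2:**
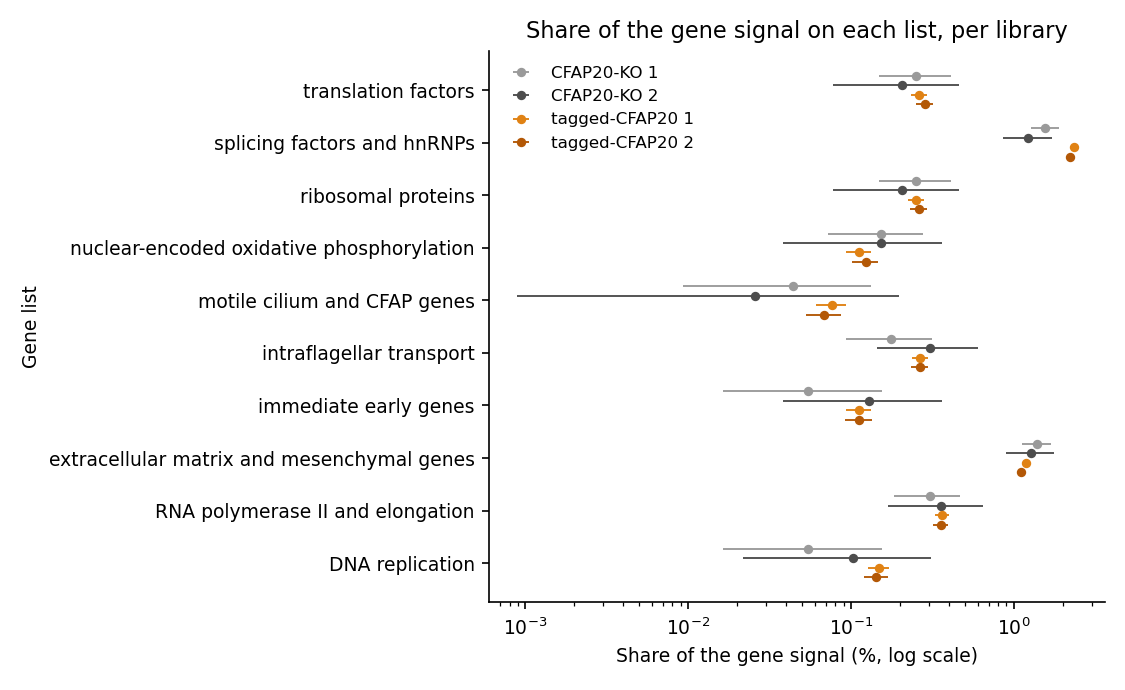
Share of each library's gene signal (percent, log scale) on the lists with at least 5 measured genes, 1 point per library with its 95% exact interval. The splicing factors and hnRNPs hold 2.34% and 2.22% in the tagged-CFAP20 libraries against 1.55% and 1.23% in CFAP20-KO.

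Position along the gene was compared because the deposited windows are placed relative to gene starts. Signal was higher with tagged CFAP20 in each region read. In the first 1 kb downstream of 9667 gene starts it was 2.06 ± 0.185 per bin against 0.761 ± 0.423 in CFAP20-KO (SD, n = 2), a ratio of 2.71. From 5 to 50 kb into the 1975 genes at least that long it was 1.07 ± 0.0857 against 0.559 ± 0.137, a ratio of 1.90, and from 50 to 5 kb upstream it was 0.954 ± 0.0876 against 0.434 ± 0.101, a ratio of 2.20. The start region over the upstream region, a contrast within each library, was 2.16 ± 0.00478 against 1.69 ± 0.583, a ratio of 1.28. The groups did not overlap in any of the 4 comparisons, which chance gives 1 time in 3, and each exact permutation p (two-sided) was 0.333, the smallest that 2 against 2 libraries allow. With the same window totals the start-region ratio was 1.302, the gene-body ratio 0.879 and the upstream ratio 1.01. Without CFAP20-KO replicate 1 the start-region ratio was 1.95 and the contrast ratio 1.03, and without replicate 2 they were 4.47 and 1.70. The contrast itself was 1.28 and 2.10 in CFAP20-KO replicates 1 and 2. Trimming the highest 1% moved the start-region ratio to 9.53 and the contrast ratio to 4.10. This came mainly from the shallow CFAP20-KO libraries, whose start-region signal fell from 0.462 and 1.06 to 0.142 and 0.191. In the tagged-CFAP20 libraries it fell from 2.20 and 1.93 to 1.69 and 1.49. In genes above 0 in all 4 libraries the contrast ratio was 1.08, with overlapping groups.

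**Figure D3:**
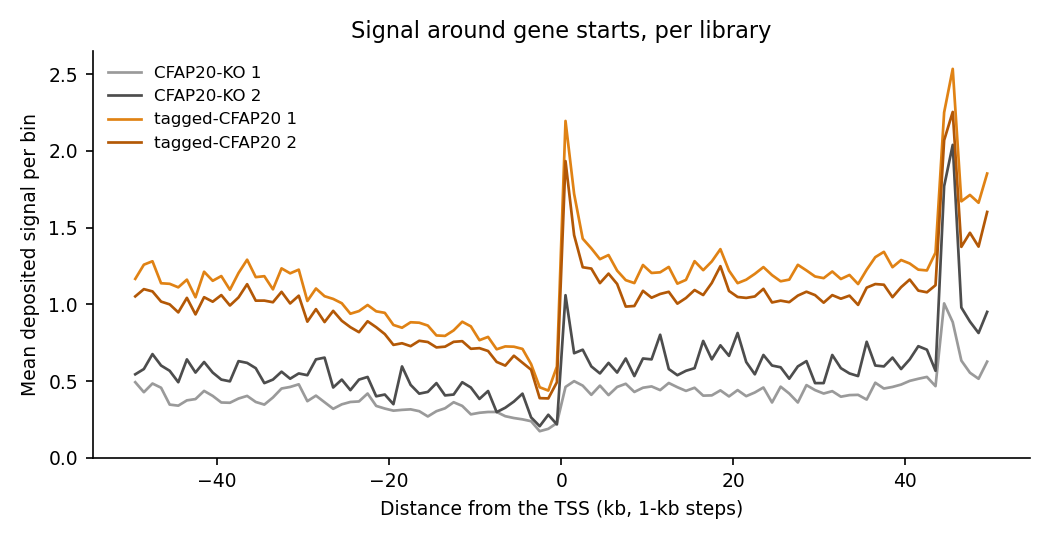
Mean deposited signal per bin in 1-kb steps against distance from the gene start (kb), 1 line per library over 9667 genes. The tagged-CFAP20 libraries lie above CFAP20-KO at the start, 2.06 against 0.761 over the first 1 kb, and 38.9% to 49.6% of each library's signal from 44 to 50 kb comes from 1 window, which covers MALAT1.

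Annotated features under the reads were compared after the data were seen. Coding exons took a larger share of read overlaps with tagged CFAP20, 33.7% and 33.1% against 22.3% and 25.6% in CFAP20-KO. The 3′ UTRs took less, 6.43% and 6.87% against 10.8% and 8.69%, as did long noncoding RNA exons, 6.76% and 6.65% against 7.90% and 9.56%. Introns held 45.4% and 45.5% against 50.5% and 47.7%, 5′ UTRs 2.35% and 2.29% against 1.61% and 1.89%, and bins between genes 3.93% and 4.11% against 5.04% and 4.82%. Inside the same genes, the odds of a read lying on coding bins rather than the 3′ UTR were 1.99 times higher with the tagged protein (95% bootstrap interval over genes 1.85 to 2.12), and above 1 in all 4 pairs of a tagged-CFAP20 with a CFAP20-KO library. Against introns the ratio was 1.33 (1.24 to 1.41), and against the 5′ UTR it was 0.991 (0.870 to 1.10). These intervals leave out the spread between libraries. Single pairs ran from 1.56 to 2.25 against the 3′ UTR and from 1.17 to 1.41 against introns. Between the 2 CFAP20-KO libraries the odds ratios were 0.776 and 0.831. With all genes summed, the ratios of the groups were 2.24 and 1.54. No p is given for these shares, since a permutation test of 2 against 2 libraries cannot go under 0.333.

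**Figure D4:**
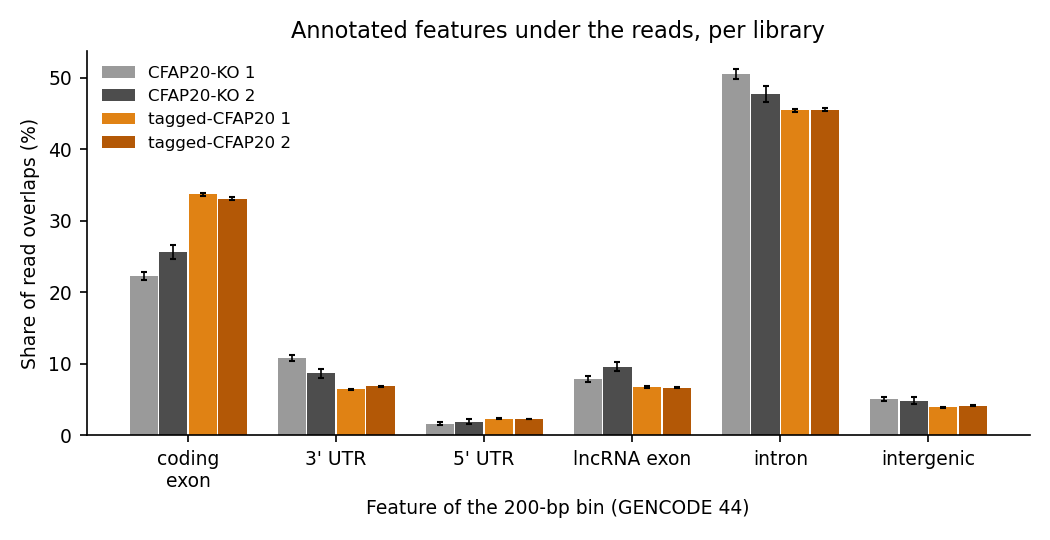
Share of read overlaps (percent) by the annotated feature of the 200-bp bin, 1 bar per library with its 95% exact interval. Coding exons hold 33.7% and 33.1% in the tagged-CFAP20 libraries against 22.3% and 25.6% in CFAP20-KO.

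Replicate agreement was read across the 4461 genes, which are not independent replicates. The tagged-CFAP20 libraries had a Pearson r of 0.921 and a Spearman rho of 0.932 with each other. The CFAP20-KO libraries had 0.467 and 0.471, below the r of 0.565 to 0.650 between libraries of different groups. With every library thinned to the shallowest, r was 0.577 between the tagged-CFAP20 libraries and 0.345 between the CFAP20-KO libraries. Replicates differed beyond sampling noise in single bins with many overlaps. They were kept as separate libraries in limma and the permutation tests, while the exact tests pooled them. The chi-square per degree of freedom was 1.14 (tagged-CFAP20) and 1.28 (CFAP20-KO) over gene sums, and 2.32 and 8.503 over the 315 and 9 single bins with enough overlaps. Reads that span 2 bins also raise the values over gene sums, so these alone do not show a spread beyond sampling. The exact tests allow for 1.28 only.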

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

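All 6 tests of explanations in this part were chosen after the results were seen, as were the feature shares, the exact tests of reads and the omission of libraries from them.

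Nearly all genes that passed in limma were higher with tagged CFAP20. The depth difference between the groups may account for part of these calls, since limma called 650 of 3867 genes in simulated libraries that had the same signal and the real depths. Depth alone is argued against by the exact test of reads, which called 0 genes in that simulation and 191 genes higher in the real libraries. The simulated genes had a set dispersion of 0.02, so this holds for that spread only. With equal shares in all simulated libraries the exact test called 145 of 2768 genes on the deposited scale, all higher. Limma called 1434 of 4030 there, although no single gene was changed. One factor per library that acts on all genes, from RNA yield or from the authors' scaling, stays open, because as shares of the gene signal only 8 genes passed, 2 higher and 6 lower. A wider recovery of RNA by the tagged protein would give the same pattern and cannot be separated from such a factor with these tables.

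Coding exons took a larger share of reads with tagged CFAP20. GC content of the bins is argued against as the cause, since both tagged-CFAP20 libraries lay above both CFAP20-KO libraries in 5 of 5 strata of GC. A few abundant coding genes are argued against as the whole cause too. Inside the same genes the odds ratio of coding against 3′ UTR bins was 1.99, against 2.24 with all genes summed. A preference of the tagged protein, or of what it is bound to, for coding parts of transcripts is a hypothesis that these data do not test, and a different origin of the background RNA in the CFAP20-KO libraries, which gave far fewer reads, stays open beside it.

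Reads on CFAP20 itself lay on coding exons with the tagged protein and on the 3′ UTR in no library. From the ratio of 3′ UTR to coding signal per bin in other genes of the tagged-CFAP20 libraries, 0.354, 7.48 overlaps on the 3′ UTR bins were predicted and 0 were seen. Genes vary in this ratio, and 0 overlaps there were also seen in 44 of 1116 other genes with a prediction within 1.5 times that of CFAP20 (3.94%), and in 3 of the 35 of these with at most 3 such bins (8.57%). An expression construct without the native 3′ UTR therefore stays open as a source of these reads, as does the knockout gene's own transcript.

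Signal outside the deposited gene set was read from neighbours' windows. Only annotated genes whose tagged-CFAP20 libraries both lay above both CFAP20-KO libraries were taken. FN1 and GAS5, at 1.03 and 0.651 times the CFAP20-KO signal, did not meet this. TALAM1 met it but is not counted separately here, since it overlaps MALAT1 and shares its reads. Of the other genes, the 10 with most signal in tagged-CFAP20 follow. Among noncoding RNAs of the nucleus, MALAT1 had 1.62 times the CFAP20-KO signal (226137 ± 24945 against 139553 ± 65775, SD, n = 2), with TALAM1 overlapping it on the other strand, and NEAT1, the scaffold of paraspeckles, 1.29 times. SRRM2, a protein of nuclear speckles, stood at 3.97 times (24357 ± 1382 against 6131 ± 2685), and DDX5, an RNA helicase, at 3.62 times. Among genes of the cytoskeleton and adhesion, ITGA3 stood at 3.31, MYH9 at 2.58, ACTN4 at 2.34 and TPM1 at 1.77 times. FAM20C, a secretory pathway kinase, stood at 1.37 times and HMGA2, a chromatin protein, also at 1.37 times. As shares of each library's reads, exact tests passed for SRRM2 (2.04-fold higher, adjusted p = 5.07e-05), NEAT1 (0.608 times, adjusted p = 1.04e-09) and MALAT1 (0.845 times, adjusted p = 0.000112), and MALAT1's shares in the CFAP20-KO libraries were themselves apart, at 4.34% and 6.07% against 4.16% and 4.04%. SRRM2 and NEAT1 did not pass without CFAP20-KO replicate 1, and MALAT1 did not pass without CFAP20-KO replicate 2.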

How the results depend on the processing

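The exact tests of reads, thinning, precision weights, the filter on mean reads and the pseudocount of 1 read were chosen after seeing the data, and the other settings before. The start-region, upstream and start-over-upstream ratios stayed above 1 under all settings run, and the gene-body ratio under all but equal window totals (0.879), but no setting could give a p under 0.333. They ranged over omitted libraries from 1.95 to 4.47, 1.89 to 2.63, 1.03 to 1.70 and, for the gene body, 1.62 to 2.304. Trimming moved the start region to 9.53 and the contrast to 4.10, mainly through a fall in the signal of the shallow CFAP20-KO libraries. In genes above 0 in all 4 libraries the contrast was 1.08 with overlapping groups. The 1681 genes called by limma became 0 with quantile normalization (15.96% of genes at an unadjusted p under 0.05) and 0 in genes above 0 in all 4 libraries (262 of 1119 unadjusted), 0 to 3674 over omitted libraries (24 and 41 unadjusted without tagged-CFAP20 replicates 1 and 2; a lone library is assumed to vary like the other group), 1046 with the pseudocount of 1 read, 288 after thinning, 276 and 295 with precision weights on the deposited and window total scales, 56 with the filter on mean reads, and 193 and 8 in the exact tests, which ranged from 0 to 232 and 0 to 7 over omitted libraries. With equal window totals limma called 1483 genes, 1451 higher and 32 lower. The cause of these differences in number was not tested, except that fewer genes enter after the filters and thinning. Camera's 0 lists became 9 with fry, which does not compare a list with other genes, 1 with precision weights on the window total scale (splicing factors and hnRNPs, adjusted p = 1.06e-05, and 0.357 with an estimated correlation) and 0 to 1 over omitted libraries. Thinned, r was 0.345 and 0.577. Signs turned in 55 values of 26 genes without a call in either fit and, with a call in at least 1 fit or over omitted libraries, for EXT1 (-0.49 with quantile normalization, -0.60 with equal window totals, -0.69 with weights on that scale), ITGA11 (-0.86, -0.94) and PICALM (-0.59), which pass as lower there,, ZMIZ1 (-0.024, -0.10), DDX17 (-0.11), CCAT1 (-0.87 with quantile normalization, -0.37 over the whole downstream side, -1.92 and -3.06 with weights), BAX (-1.77 to 4.05 over omitted libraries), and, over the first 3 kb, ENSG00000272369 (1.95) and RPS4X (4.19). The replicate block gave 1874 genes higher and 0 lower, so NORAD (limma adjusted p = 0.165), ENSG00000272369 (0.0712) and IRAG1 lost the call, with 0 lists. Its ratios were 2.94 for the start region, 1.93 for the gene body, 2.23 upstream and 1.32 for start over upstream. The replicate numbers share no stated culture, and deviations of same-numbered libraries had an r of 0.0054. Of 73 named genes tested, 23 passed, and 3 reads in CFAP20-KO replicate 2 are worth a signal of 1145.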

Other observations

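The share test of all annotated genes in this part was chosen after the results were seen, as was leaving out each library from it.

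Among 4166 annotated genes read from the joined windows, 25 differed in their share of the reads, 2 higher and 23 lower with tagged CFAP20 (exact binomial test), and 212 had an unadjusted p under 0.05. The signal is not split by strand, so 10 of the 23 lower genes form 5 overlapping pairs that share reads (MALAT1 with TALAM1, RN7SL1 with RPS29, RN7SL2 with ENSG00000282885, ENSG00000272369 with SLC38A4-AS1, LOX with SRFBP1). Both higher genes encode proteins of RNA processing, SRRM2 (2.04-fold) and HNRNPH1 (2.84-fold). The lower ones included noncoding RNAs. GAS5, the host of several small nucleolar RNAs, fell to 0.304 times its CFAP20-KO share, from 0.538% and 0.515% to 0.163% and 0.159% (adjusted p = 1.32e-20). The signal recognition particle RNAs RN7SL1 and RN7SL2 fell to 0.123 and 0.212 times, but they have many near-identical copies, so their values are uncertain.

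Further lower genes are named here after their values were seen, and they were not tested as a group. The fixed list of extracellular matrix and mesenchymal genes did not pass in camera (adjusted p = 0.115). FN1, which encodes fibronectin, fell to 0.445 times its CFAP20-KO share, from 1.22% and 0.877% to 0.505% and 0.490% (adjusted p = 1.60e-22), while its signal on the deposited scale was 27439 ± 3021 against 26543 ± 445 (SD, n = 2), a ratio of 1.03. LOX fell to 0.225 times, EFEMP1, a fibulin, to 0.334 times and WWTR1, the Hippo pathway coactivator TAZ, to 0.321 times. SCD, the stearoyl-CoA desaturase, fell to 0.345 times (adjusted p = 0.000143). SPARC passed at 0.419 times, although its shares in the tagged-CFAP20 libraries, 0.0520% and 0.0577%, lay between those of the CFAP20-KO libraries, 0.170% and 0.0362%. Of the 25 genes, 17 lie outside the deposited gene set, 1 higher and 16 lower. Without CFAP20-KO replicate 1 the test called 5 annotated genes, GAS5, MALAT1, PDLIM5, RN7SL1 and TALAM1, and without CFAP20-KO replicate 2 it called 16, among them GAS5, RN7SL1, FN1, SCD, SRRM2 and HNRNPH1 but not MALAT1, LOX, EFEMP1 or WWTR1. Without tagged-CFAP20 replicates 1 and 2 it called 21 and 24.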
